A study of Mus musculus and Danio rerio
Mus musculus with 21 samples.

How the data were processed

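Agilent 2-colour arrays of 21 samples were used, 13 on a mouse design with 41174 probes and 8 on a zebrafish design with 43803. Per the labels' protocols, RNA was extracted with miRNeasy and 500 ng of total RNA were amplified with a Quick Amp kit and spike-in controls. The sample was labelled with Cy3 and a pooled common reference with Cy5, in 1 orientation: pooled RNA of cultured MSCs for the mouse arrays and of injected embryos for the zebrafish arrays. Per the labels, the 6 populations are B6-BMMSC and BC-BMMSC, each at low and high passage, TmMSC, and S1d/s from metastases of TmMSC tumours. The passages of a line are thus related, as are TmMSC and S1d/s, and they are not independent replicates. Each population had 1 array per setting, so n counts arrays and every p measures only these samples. Low-passage B6-BMMSC and BC-BMMSC formed the low-passage group, their high-passage cells the high-passage group, and TmMSC and S1d/s the tumour-derived group. That last name is shorthand: TmMSC formed tumours when injected into mice, and only S1d/s came from them per the labels. Strain and population went together, since BALB/C was represented by BC-BMMSC alone.

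Per the file headers, the scans were read with Feature Extraction 10.7.3.1, which gave the median spot and background intensity of each channel. The log10 values of the series matrix, as deposited by the authors, were the log10 ratio of Cy5 to Cy3 of the same software, with a largest difference of 0 from the files. Their medians were 0 on every mouse array and between -0.0115 and 0.0536 on the zebrafish arrays, so values of the 2 designs were never put in 1 fit. Hybridisation and washing steps beyond the stated kit are not given in the sources used here.

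From the files, median intensities were used because mean spot signals were not among the columns. Background was corrected with limma's normexp and an offset of 50, and the log2 ratio of sample to reference was computed. Cultured cells and zebrafish arrays were normalized by loess within array. Mouse arrays of embryos were not, since most of their probes carried embryo signal, and were centred on the median of the probes tested for injected against cultured cells. A probe was tested if its Cy3 signal was well above background on at least 2 arrays of the fit. For injected against cultured cells it had to be so on all 6 injected arrays, and for mouse genes in embryos by condition on at least 2 of them, and in both not on the uninjected-embryo array. A gene was represented by the probe with the highest mean signal. Symbols came from the RefSeq table given: 26711 mouse probes (64.9%) carried one, for 18218 genes, and none of the zebrafish probes, so the 19 zebrafish lists could not be tested. A gene order from the same table was used for neighbours only.

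Groups were compared with limma's moderated linear models, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Injected and cultured arrays were paired by population. A 3-group fit was used for high-passage and tumour-derived cells apart. Where a probe was not well above background on any array of a group, the difference is given as a bound from Cy3 signal. Gene lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Where slide was a random block, camera was replaced by its preranked form on moderated t, since camera takes no such block. S1d/s against TmMSC had 1 array each and got no test; each list's median was placed among 10000 random lists matched on level.

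The lists, comparisons, the rule for naming genes and most alternatives were choices made before the data were examined; the alternatives chosen later are named with their values. Named were genes with a symbol past adjusted p of 0.05 whose groups did not overlap (paired: the same sign in all 6 pairs), the 10 largest rises and 10 largest falls. Where fewer than 5 passed in a direction, the 5 largest differences among genes without overlap were given as values. From each list up to 4 members past the threshold, or else the 2 largest, were taken, and always Mmp19, Ets1, Cdkn2a, Cdkn2b, Trp53, Mki67 and Col1a1. For S1d/s against TmMSC it was the 5 largest in each direction. Of the genes the rule names, 3 are not reported here. Genes outside this rule are marked as chosen after their values were seen.

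Pairing came from the labels, which give the same cell line at both passages and the same population in culture and embryo. Deviations of low- and high-passage cells of the same line correlated at 0.50 over 22319 genes. Those of the injected and cultured arrays of a population correlated at -0.088 for low-passage B6-BMMSC, 0.022 for high-passage B6-BMMSC, 0.14 for low-passage BC-BMMSC, -0.019 for high-passage BC-BMMSC, -0.059 for TmMSC and 0.12 for S1d/s over 298 genes.

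The fits were tested on simulated data with known changes. At log2 changes of 1, 2 and 3, 25.4, 53.7 and 75.8% of changed genes were recovered for cultured cells by condition, 93.9, 100 and 100% for injected against cultured cells, 56.7, 71.6 and 90.9% for cell-injected against PVP-injected embryos and 40.3, 89.6 and 95.5% for zebrafish transcripts of embryos by condition. Mouse genes in embryos by condition were not simulated. Of 22 lists, 0 were called with no change added. Genes were simulated as independent, though, and the estimated spread of each gene was taken as its true one. In cultured cells by condition the estimated correlation was 0.75 for cell cycle and 0.80 for interferon response. The count of lists called therefore does not test the preset correlation of 0.01. For the same reasons the recovered shares do not give the power of the real fits. Cy3 signal over background was weak in embryos: the median background-subtracted signal was 35.5 to 45.5 on cultured and 10.7 to 17.1 on injected mouse arrays. No spot was saturated, and the PVP array had 585 non-uniform spots. Slides were inferred from the scan partition of the files, and no label names a slide.

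Alternatives covered the software's processed signals, other scalings, Cy3 alone, spike-in scaling, stricter and looser filters, the authors' deposited ratios, every probe, slide and strain as blocks, fits with and without the pairing, and each array left out in turn. Used were R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.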

Results

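Gene expression was measured in 6 populations of mouse mesenchymal stem cells (MSCs), stromal cells that can form bone, cartilage and fat, in culture and after injection into zebrafish embryos. B6-BMMSC cells of C57BL/6 mice were taken at passages 9 and 28, and BC-BMMSC cells of BALB/C mice at passages 14 and 34. The labels call the low-passage cells normal and the high-passage cells transformed. TmMSC cells formed osteosarcoma, a bone tumour, when injected into mice, and S1d/s cells came from lung metastases of those tumours. The stated design set low-passage cells against high-passage and tumorigenic cells, in the dish and in the embryo. Mouse arrays carried RNA of the 6 cultured populations, of embryos injected with each of them, and of uninjected embryos. Zebrafish arrays carried RNA of embryos injected with each population, of embryos injected with PVP alone, and of cultured high-passage BC-BMMSC cells. Every population had 1 array per setting, so each tested comparison rested on 6 to 12 arrays, and that number limited its precision.

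The mouse arrays detected far less in embryos than in culture once the signal of embryo RNA was set apart. Cy3 signal was well above background on 63.5 to 68.0% of 41174 mouse probes with cultured-cell RNA, on 55.7 to 61.3% with injected-embryo RNA, and on 53.03% with RNA of uninjected embryos. Of 18143 probes well above background on all 6 injected arrays, 17843 were so on the uninjected array too. The ratios of the injected arrays correlated with those of the uninjected array at r = 0.90 to 0.99 across probes, which are not independent replicates. On the 500 probes brightest in culture among those not above background with uninjected-embryo RNA, the signal above the uninjected array had a median of 0.49% of the cultured level for low-passage B6-BMMSC, 0.086% for high-passage B6-BMMSC, 0.49% for low-passage BC-BMMSC, 0.75% for high-passage BC-BMMSC, 0.61% for TmMSC and 0.57% for S1d/s. Scaled by the spike-in probes the medians were, in the same order, -0.0044, -0.013, 0.078, 0.10, 0.075 and 0.084%. On the zebrafish arrays, 82.0 to 86.9% of 43803 probes were well above background in cell-injected embryos, 71.9% in PVP-injected embryos and 14.2% with mouse RNA.

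**Figure D1:**
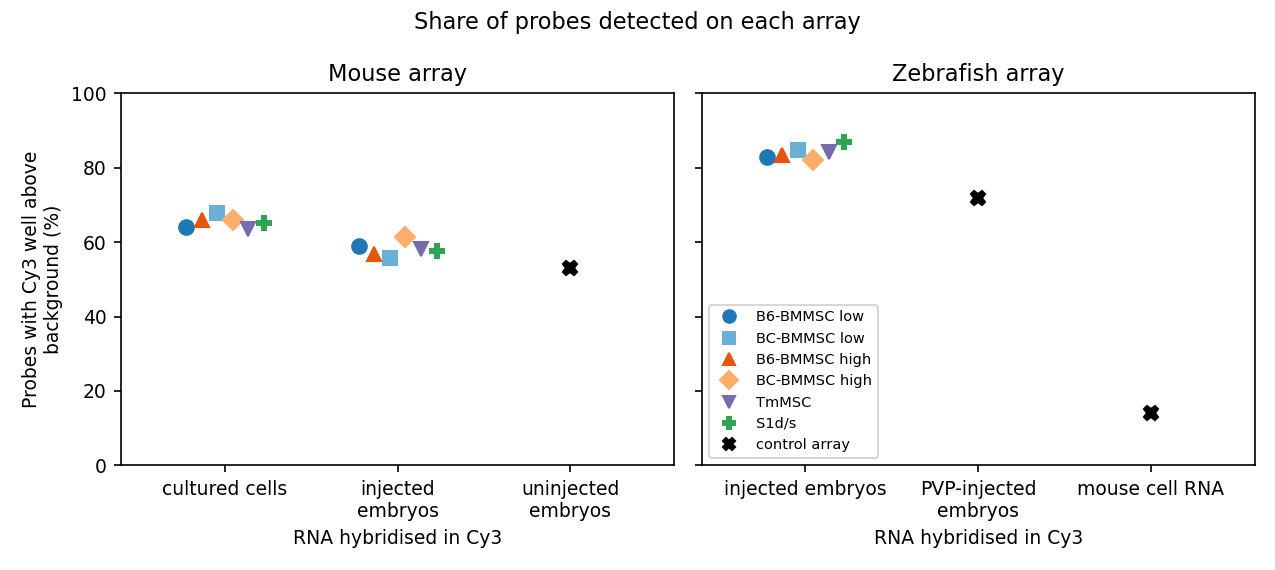
Share of probes (percent) with Cy3 signal well above background on each array, mouse arrays in one panel and zebrafish arrays in the other, 1 point per array. Uninjected-embryo RNA lit 53.03% of the mouse probes, close to the 55.7 to 61.3% of the injected embryos, and mouse RNA lit 14.2% of the zebrafish probes.

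Cultured high-passage and tumour-derived cells were compared with low-passage cells to ask how expression differs between transformed and normal MSCs. Cell cycle genes rose: 29 of 29 measured members were higher, with a median log2 difference of 1.05, among them the cyclin Ccna2 (1.61 ± 0.50, SE, n = 4 against 2) and the replication helicase subunit Mcm6 (1.53 ± 0.36). Ribosomal protein genes rose by a median of 0.50 (19 of 23 higher; Rpl4 1.43 ± 0.37, Rps6 0.90 ± 0.19), hypoxia and glycolysis genes by 0.63 (15 of 19; the glycolytic enzyme Eno1 1.78 ± 0.75). Interferon response genes rose by 0.91 (24 of 25; Cxcl10 1.87 ± 2.02, Psmb8 1.52 ± 0.80) and MHC class I genes by 0.44 (9 of 11; H2-D1 1.67 ± 0.54, H2-M3 1.23 ± 0.47). Cholesterol synthesis genes rose by 0.40 (14 of 18; Cyp51 1.06 ± 0.52, Fdps 1.02 ± 0.47). Matrix and collagens fell as a group (median -0.66, 26 of 29 lower), with Fbln2 at -3.10 ± 1.79 and the microfibril gene Mfap5 at -2.77 ± 0.72. The hypoxia gene Adm went against its list, at -3.39 ± 1.62. These 7 of 22 lists were called by limma's camera with a preset correlation, at adjusted p of 3.41e-12 for cell cycle, 7.03e-07 for ribosomal proteins, 0.00724 for hypoxia and glycolysis, 0.00858 each for matrix and collagens, interferon response and MHC class I, and 0.0344 for cholesterol synthesis. None held with an estimated correlation (adjusted p = 0.83 for each). No member passed the test over all genes, and adjusted over the list alone the count was 0 in each of the 7 lists.

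Low-passage B6-BMMSC carried much of the cell cycle difference. The mean over the list, relative to the mean of the 2 low-passage arrays, was -0.63 in low-passage B6-BMMSC and 0.63 in low-passage BC-BMMSC, against 0.32 and 1.32 in their high-passage cells, 1.43 in TmMSC and 1.04 in S1d/s. Without low-passage B6-BMMSC the difference was 0.39. The interferon response mean was 2.90 in high-passage B6-BMMSC and 1.77 in S1d/s but -1.30 in high-passage BC-BMMSC. On the 2 slides, as inferred from the files, that held both conditions the mean differences were 1.95 and 0.80 for cell cycle, 0.50 and 0.36 for ribosomal proteins, 0.24 and 0.50 for hypoxia and glycolysis. They were -1.05 and -0.15 for matrix and collagens, -0.14 and 1.02 for MHC class I, 0.77 and -0.28 for cholesterol synthesis and -1.98 and 0.56 for the interferon response. Each of these is 1 array against 1 of another line: high-passage BC-BMMSC against low-passage B6-BMMSC, then TmMSC against low-passage BC-BMMSC. High-passage B6-BMMSC and S1d/s were alone on their slides. With slide as a block, which rests on the same 2 pairs, 3 lists stayed called. Their medians were 1.41 for cell cycle, 0.34 for ribosomal proteins and 0.55 for hypoxia and glycolysis. Matrix and collagens (-0.065), interferon response (-0.82), MHC class I (0.24) and cholesterol synthesis (0.20) were no longer called. Strain as a block ended the calls of interferon response (0.27) and MHC class I (0.28). Leaving out S1d/s ended those of matrix and collagens (median -0.28), interferon response (0.56), hypoxia and glycolysis (0.27) and cholesterol synthesis (0.24). Leaving out high-passage B6-BMMSC ended matrix and collagens (-0.55), interferon response (0.13) and MHC class I (0.16). Leaving out low-passage B6-BMMSC ended matrix and collagens (-0.81) and cholesterol synthesis (-0.15), and low-passage BC-BMMSC ended interferon response (0.20) and hypoxia and glycolysis (0.36). The p53 targets list was called higher without low-passage B6-BMMSC (0.47) and lower without low-passage BC-BMMSC (-1.01), where CDK inhibitors (-0.97) were called lower too. Matrix proteases and inhibitors (-0.73) were called lower without TmMSC.

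**Figure D2:**
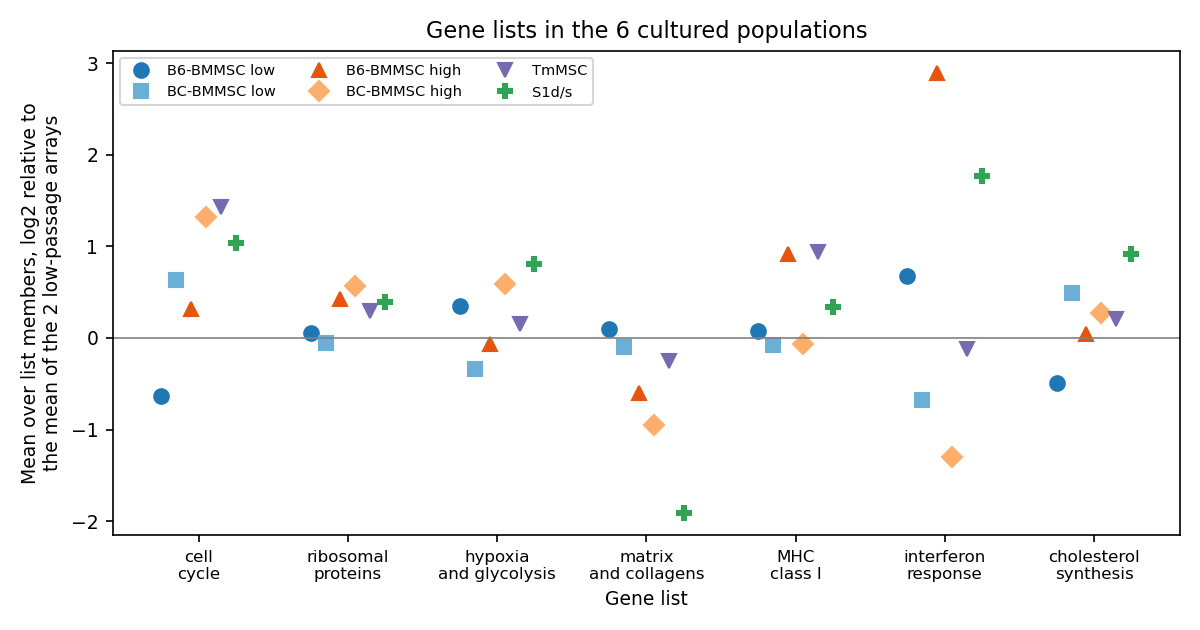
Mean log2 level over the members of each of the 7 called gene lists in each cultured population, relative to the mean of the 2 low-passage arrays, 1 point per array. Cell cycle and ribosomal protein means of the 4 high-passage and tumour-derived populations lie above 0, while the interferon response spans -1.30 to 2.90.

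Of the 15 lists that were not called, p53 targets had a median of -0.31 (18 of 25 lower; Btg2 -1.36 ± 0.92, Perp -1.35 ± 1.02) and CDK inhibitors of -0.82 (6 of 7 lower; Cdkn1c -0.93 ± 0.62). Matrix proteases and inhibitors had a median of -0.43 (18 of 24 lower; Adamts1 -1.65 ± 0.53, Mmp14 -1.49 ± 0.56) and Wnt pathway genes of -0.40 (Rspo2 -3.15 ± 1.58, Sfrp1 -2.60 ± 1.48). Lineage markers had medians of 0.063 for osteoblast (Spp1 1.66 ± 1.53, Msx2 -1.17 ± 0.97) and 0.083 for adipocyte genes (Lpl -2.35 ± 1.26, Cebpa -1.06 ± 0.46). Chondrocyte genes had one of -0.24 (Comp -1.30 ± 0.67, Col11a2 -0.75 ± 0.22) and MSC surface and stroma one of -0.26 (Thy1 -1.99 ± 2.15, Nt5e 1.78 ± 0.59). A median near 0 can hide arrays that differ. Relative to the low-passage arrays, the osteoblast mean was 0.95 in TmMSC, -0.32 in S1d/s, and -0.42 and -0.20 in high-passage B6-BMMSC and BC-BMMSC. Angiogenic factors had a median of -0.11 (Thbs1 -2.1002 ± 0.80, Vegfd -1.96 ± 1.02), and inflammatory cytokines one of 0.33 (Cxcl1 1.64 ± 1.08). Il1rl1, a receptor of the interleukin-1 family, was the only member of any list to pass adjusted over the list alone (1.32 ± 0.26, limma adjusted p = 0.0331). Markers of other cell types had medians of -0.13 for macrophage and haematopoietic cells, -0.15 for endothelial, -0.00046 for epithelial and -0.22 for skeletal muscle cells. Heat and cold stress genes had a median of 0.24 and a mean of -0.13, with the inducible Hsp70 genes Hspa1a at -3.46 ± 1.28 and Hspa1b at -2.11 ± 0.76. For adipocyte the median and camera pointed up and the mean (-0.16) down, and for angiogenic factors and epithelial genes camera pointed up and the median and mean down.

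Among single genes, the largest rises without overlap of the groups were those of Brinp3 (2.99 ± 0.60) and the water channel Aqp1 (2.90 ± 1.14). Next came Rgs17, a regulator of G-protein signalling (2.29 ± 1.19), Errfi1, a feedback inhibitor of the EGF receptor (2.14 ± 0.34), and Plcl2 (2.103 ± 0.80). The largest negative differences were those of the adhesion protein gene Svep1 (-3.74 ± 1.26), the protein kinase A scaffold Akap12 (-3.71 ± 1.56), the glutamate transporter Slc1a6 (-3.55 ± 0.96), Hspa1a and the intermediate filament gene Synm (-3.39 ± 1.49). None passed: limma called 0 of 22331 genes, with a smallest adjusted p of 0.612, and 1818 genes had an unadjusted p under 0.05. In 4171 genes (18.7%) the groups did not overlap, where chance gives 13.33% for 2 arrays against 4. Without high-passage B6-BMMSC 3 genes passed, the imprinted genes Kcnq1ot1 (-4.76) and Peg12 (-4.43) and 1 transcript with no symbol (-3.35), named here after their values were seen.

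The genes named in every comparison were measured on all 6 cultured arrays. The study's own candidates, chosen on these samples and so not independent evidence, were Mmp19, a matrix metalloproteinase, at -0.92 ± 0.62 (limma adjusted p = 0.70), and Ets1, a transcription factor, at 0.37 ± 0.19 (limma adjusted p = 0.63), with 1 of its 3 probes pointing the other way. Mmp19 was at -0.39 and -0.91 in low- and high-passage B6-BMMSC, 0.51 and -1.17 in BC-BMMSC, 0.37 in TmMSC and -1.72 in S1d/s, as log2 ratios to the reference. The proliferation marker Mki67 differed by 0.97 ± 0.64, Trp53, the p53 gene, by -0.31 ± 0.38 and the collagen gene Col1a1 by -0.88 ± 0.84. Low-passage B6-BMMSC carried the Mki67 difference. Mki67 stood at -2.06 and -0.71 in low- and high-passage B6-BMMSC, 0.028 and -0.14 in BC-BMMSC, 0.15 in TmMSC and 0.52 in S1d/s. The cell cycle inhibitors Cdkn2a (-0.86 ± 1.69, limma adjusted p = 0.91) and Cdkn2b (-1.85 ± 2.55, 0.86) divided the populations otherwise than by condition. Cdkn2a stood at 1.68 and 2.21 in low- and high-passage B6-BMMSC and at -2.07 and -2.08 in BC-BMMSC, -2.16 in TmMSC and -2.20 in S1d/s. Cdkn2b stood at 1.69 and 0.99 in B6-BMMSC and between -5.01 and -4.93 in the other 4. Of 16 measured genes from Mllt3 to Cdkn2b, taken in chromosomal order after the values were seen, Mllt3, Focad, Hacd4, Klhl9 and Mtap were also lower by over 1 on the log2 scale in both BC-BMMSC arrays than in either B6-BMMSC array. In embryos these genes had no value of their own, since their probes were well above background with uninjected-embryo RNA too, except 1 Ets1 probe (-0.24 ± 0.17, limma adjusted p = 0.32).

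**Figure D3:**
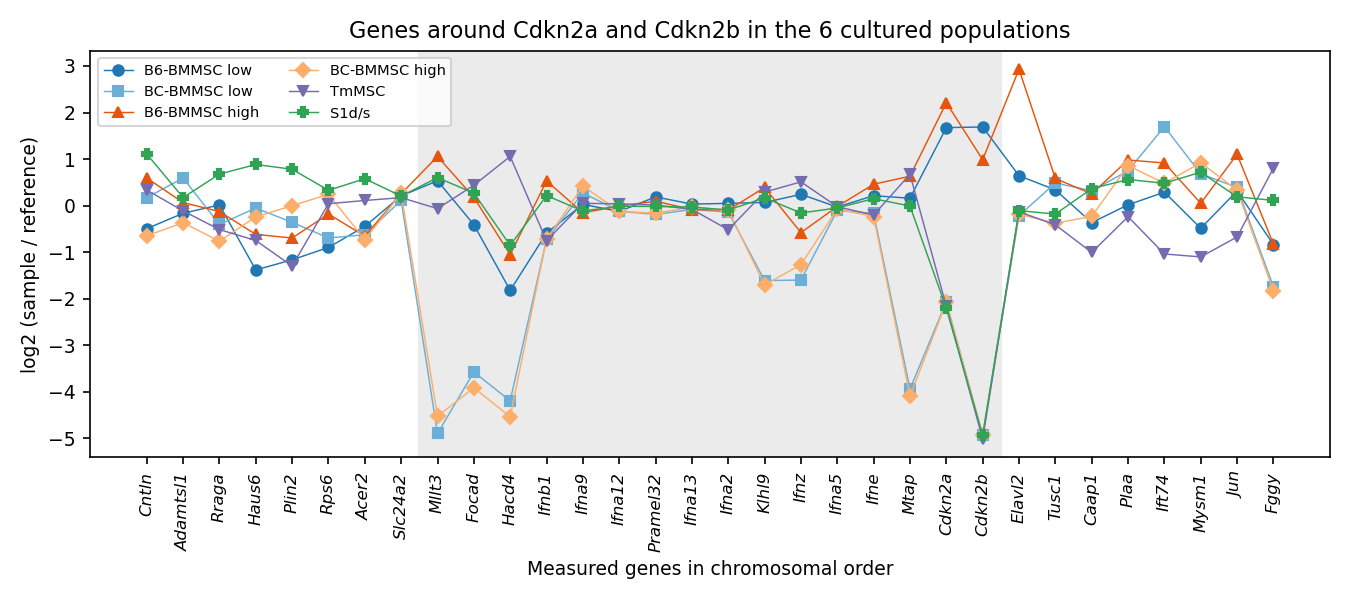
Log2 ratio of sample to common reference for 32 measured genes around Cdkn2a and Cdkn2b in chromosomal order, 1 line per cultured population, with the 16-gene segment shaded. Both BC-BMMSC cultures drop at Mllt3, Focad, Hacd4, Klhl9, Mtap, Cdkn2a and Cdkn2b, while TmMSC and S1d/s drop at Cdkn2a and Cdkn2b.

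Between high- and low-passage cells of the same lines, ribosomal protein genes rose by a median of 0.52 (22 of 23 higher; Rpl4 1.52 ± 0.46, Rpl8 0.89 ± 0.31, SE, n = 2 against 2) and cell cycle genes by 0.86 (28 of 29; the helicase subunits Mcm5 1.27 ± 0.55 and Mcm2 1.26 ± 0.56). Interferon response genes rose by 0.87 (23 of 25; Cxcl10 1.56 ± 2.56, Zbp1 1.27 ± 1.26) and MHC class I genes by 0.52 (8 of 11; H2-D1 1.35 ± 0.62, the peptide transporter Tap1 1.0998 ± 0.67). Matrix and collagens (median -0.55, 26 of 29 lower; Fmod -2.36 ± 1.30, Postn -2.25 ± 1.46) and matrix proteases and inhibitors (-0.68, 18 of 24 lower; the collagenase Mmp13 -2.65 ± 2.96, Mmp3 -1.31 ± 1.39) fell. The camera adjusted p was 1.29e-10 for ribosomal proteins (0.305 with an estimated correlation), 7.18e-09 for cell cycle, 0.0105 for matrix and collagens, 0.0275 for interferon response, 0.0435 for MHC class I and 0.0455 for matrix proteases and inhibitors, the last 5 with adjusted p = 0.96 with an estimated correlation. With the cell line as a block matrix proteases and inhibitors were not called (limma camera adjusted p = 0.197, over 15 alternatives 0.00260 to 0.839). Adjusted over the list alone the count was 0 in every list.

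Within each line the cell cycle mean was 0.95 higher at high passage in B6-BMMSC (27 of 29 members) and 0.68 in BC-BMMSC (25 of 29), and the ribosomal protein mean 0.37 (22 of 23) and 0.64 (19 of 23). The interferon response mean was 2.22 higher in B6-BMMSC and moved by -0.63 in BC-BMMSC, and the MHC class I mean was 0.84 higher in B6-BMMSC (10 of 11) and 0.0071 in BC-BMMSC (5 of 11). Single genes were ranked among those without overlap of the groups. Aqp1 (2.96 ± 1.46), Rhox5 (2.68 ± 1.12), Mogat2 (2.51 ± 0.85), Brinp3 (2.48 ± 0.60) and the prostaglandin transporter Slco2a1 (2.31 ± 1.33) had the largest positive differences. The thyroid hormone deiodinase Dio3 (-3.91 ± 1.99), Svep1 (-3.68 ± 1.60), the secreted Wnt antagonist Sfrp1 (-3.51 ± 1.69), Plxdc2 (-3.39 ± 2.18) and Parm1 (-3.09 ± 0.97) had the largest negative ones. Limma called 0 of 22331 genes (smallest adjusted p = 0.9997), with 763 at an unadjusted p under 0.05. Without low-passage B6-BMMSC the calls of cell cycle (median 0.23), matrix and collagens (-0.38) and matrix proteases and inhibitors (-0.34) ended. Without high-passage B6-BMMSC those of matrix and collagens (-0.61), matrix proteases and inhibitors (-0.66) and MHC class I (-0.14) ended and interferon response turned (-1.34). Without low-passage BC-BMMSC matrix proteases and inhibitors (-0.61), interferon response (0.35) and MHC class I (0.27) were not called, and without TmMSC or S1d/s MHC class I (0.52) was not. New calls were p53 targets (0.68), hypoxia and glycolysis (0.69) and cholesterol synthesis (-0.24) without low-passage B6-BMMSC, and hypoxia and glycolysis (0.56) without high-passage B6-BMMSC. Further ones were p53 targets (-0.70) and cholesterol synthesis (0.83) without low-passage BC-BMMSC, and inflammatory cytokines (1.26) without high-passage BC-BMMSC. Median and camera differed in sign for p53 targets (-0.080), MSC surface and stroma (-0.30), adipocyte (-0.024) and endothelial genes (-0.014), each of which camera put upward, and heat and cold stress had a median of 0.10 and a mean of -0.073.

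TmMSC and S1d/s, the tumour-forming cells and the cells of their metastases, were also set against the low-passage cells, which this comparison shares with the previous one, so that their values are not independent. S1d/s descended from TmMSC, so n = 2 counts arrays and not independent lines. Cell cycle genes rose by a median of 1.27 (29 of 29 higher; Ccne2 2.01 ± 0.85, Ccna2 1.99 ± 0.53, SE, n = 2 against 2), with camera adjusted p of 3.86e-11. Hypoxia and glycolysis (0.75, 15 of 19; Eno1 1.86 ± 0.96, against Adm at -5.04 ± 1.36), cholesterol synthesis (0.53, 15 of 18; Cyp51 1.52 ± 0.52, Fdps 1.44 ± 0.44) and ribosomal protein genes (0.31, 17 of 23; Rpl4 1.33 ± 0.46, Rps14 1.06 ± 0.31) rose at 0.00396 each. MHC class I genes (0.58, 9 of 11; H2-D1 1.98 ± 0.62, H2-M3 1.46 ± 0.55) rose at 0.0127 and interferon response genes (0.87, 23 of 25; Psmb8 2.31 ± 0.70, Cxcl10 2.18 ± 2.56) at 0.0310, and matrix and collagens (-0.69, 21 of 29 lower) fell at 0.0206. With an estimated correlation each had adjusted p = 0.84. Adjusted over the list alone 5 members passed, named here after their values were seen: Mcm6 (1.92, limma adjusted p = 0.0480), the matrix genes Fbln2 (-5.28), Mfap5 (-3.46) and Col4a1 (-3.15, 0.0431 each), and the protease Adamts1 (-2.28, 0.0375). Spp1, which encodes osteopontin, differed by 2.72 ± 1.68, Tnfrsf11b by -2.22 ± 0.38, Lpl by -3.50 ± 1.21 and the protease inhibitor gene Timp3 by 2.16 ± 0.47.

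Again single genes were ranked among those without overlap of the groups. The progenitor surface marker Cd34 (4.26 ± 0.76), Rgs17 (3.88 ± 0.31), Akr1c18 (3.59 ± 1.04), Brinp3 (3.51 ± 0.60) and Nrn1 (3.43 ± 0.22) had the largest positive differences from low-passage cells. Among the largest negative differences were those of Fhl1 (-5.75 ± 0.69), the interleukin-11 receptor gene Il11ra1 (-5.59 ± 0.65), the X-inactivation RNA Xist (-5.34 ± 4.07) and Synm (-5.28 ± 0.68). Rspo2 (-4.93 ± 1.13) and Dkk3 (-4.62) were the lowest of the Wnt pathway, and Hspa1a (-4.36 ± 1.39) of the heat and cold stress list. Limma called 0 of 22329 genes (smallest adjusted p = 0.389), with 2392 at an unadjusted p under 0.05. Without S1d/s the calls of matrix and collagens (median 0.31), interferon response (-0.00026), hypoxia and glycolysis (0.50), cholesterol synthesis (0.13) and ribosomal proteins (0.18) ended, and without TmMSC that of MHC class I (0.20). Without low-passage B6-BMMSC matrix and collagens (-1.18) and cholesterol synthesis (0.053) were not called. Without low-passage BC-BMMSC interferon response (-0.028), hypoxia and glycolysis (0.44) and ribosomal proteins (0.18) were not called, and without either high-passage array matrix and collagens (-0.69) were not. New calls were p53 targets (-1.41) and CDK inhibitors (-1.33) without low-passage BC-BMMSC, osteoblast genes (0.72) without S1d/s, and matrix proteases and inhibitors (-0.85) and the Wnt pathway (-1.94) without TmMSC. Strain as a block ended the calls of interferon response (-0.63), matrix and collagens (-0.57) and MHC class I (0.18), and p53 targets (-1.21) and CDK inhibitors (-1.35) were then called lower. Angiogenic factors (median -0.22) pointed up in camera, and adipocyte (0.082), epithelial (0.057) and heat and cold stress genes (0.034) had means below 0.

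Set directly against the high-passage cells, TmMSC and S1d/s had higher cell cycle genes (median 0.38, 26 of 29; Pcna 1.36 ± 0.61, Ccne2 1.15 ± 0.85, SE, n = 2 against 2) and cholesterol synthesis genes (0.42, 17 of 18; Insig1 1.14 ± 0.57). Both rose with a camera adjusted p of 0.00170, and with adjusted p = 0.97 with an estimated correlation. This ranking, too, was of genes without overlap of the groups. The largest positive differences were those of Cd34 (4.65 ± 0.76), the transcriptional inhibitor Id4 (4.29 ± 2.18), Akr1c18 (3.84 ± 1.04), the creatine synthesis gene Gatm (3.74 ± 1.17) and Plac9a (3.50 ± 0.79). The proteoglycan gene Cspg4 was at least 19.0-fold lower, by a probe not well above background in TmMSC and S1d/s, and Il11ra1 (-5.28 ± 0.65), Fhl1 (-5.19 ± 0.69) and Xist (-4.61 ± 4.07) were lower. Xist was at 3.13 and 1.71 in low- and high-passage BC-BMMSC and between -7.04 and -6.23 in the other 4 cultures, so BC-BMMSC alone gave its differences. Ribosomal protein genes (median -0.25), p53 targets (-0.59, 23 of 25 lower; Ddit4l -1.61 ± 0.81, Mdm2 -0.99999 ± 0.64) and osteoblast genes (0.74; Spp1 2.12 ± 1.68) were not called, at adjusted p of 0.0622, 0.0622 and 0.107. With strain as a block or slide as a random block, p53 targets and osteoblast genes were called. The random block brought a call of ribosomal proteins too. Mmp19 differed by 0.37 ± 0.77, Mmp13 by 3.63 ± 2.96 and Fbln2 by -4.36 ± 1.02. Limma called 0 of 22330 genes (smallest adjusted p = 0.712), with 972 at an unadjusted p under 0.05. Without high-passage B6-BMMSC the cell cycle (median -0.23) and cholesterol synthesis (0.41) calls ended, without TmMSC that of cell cycle (0.096), and without S1d/s that of cholesterol synthesis (0.11). New calls were p53 targets without low-passage B6-BMMSC (-0.54) or low-passage BC-BMMSC (-0.59), interferon response (2.05), MHC class I (0.45) and ribosomal proteins (-0.16) without high-passage B6-BMMSC. Others were p53 targets (-0.85), CDK inhibitors (-1.098), interferon response (-2.22) and hypoxia and glycolysis (0.66) without high-passage BC-BMMSC. Without TmMSC p53 targets (-0.64), matrix and collagens (-1.16), hypoxia and glycolysis (0.52) and the Wnt pathway (-0.72) were called. Without S1d/s it was matrix and collagens (0.86), osteoblast (0.99), adipocyte (0.21) and matrix proteases and inhibitors (0.48). Median and mean differed in sign for matrix and collagens (0.038, mean -0.31), the Wnt pathway (0.35, mean -0.23), matrix proteases and inhibitors (-0.021, mean 0.17), adipocyte (0.057, mean -0.036), chondrocyte (0.0043, mean -0.29), MSC surface and stroma (0.0082, mean -0.28), macrophage and haematopoietic (0.12, mean -0.018) and epithelial genes (0.031, mean -0.56).

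S1d/s cells differed from the TmMSC cells they descended from in lower levels of matrix and bone genes and a higher interferon response, on 1 array each and so with no test. Osteoblast genes had a median log2 difference of -2.04 (4 of 17 higher), adipocyte genes one of -1.76 (1 of 9), matrix and collagens -1.74 (4 of 27), Wnt pathway genes -1.13 (4 of 16) and matrix proteases and inhibitors -0.96 (3 of 21), each at percentile 0 among 10000 random lists of like level. Interferon response genes had a median of 1.82 (21 of 24 higher, percentile 100), cholesterol synthesis genes 0.59 (16 of 18, percentile 99.7) and hypoxia and glycolysis genes 0.40 (12 of 19, percentile 97.1). MHC class I (-0.65), p53 targets (-0.54) and cell cycle genes (-0.30) lay at percentiles 0.77, 0.30 and 4.23, and MSC surface and stroma (-0.47), inflammatory cytokines (-0.55) and endothelial genes (-0.38) at 1.04, 2.39 and 2.74. The other 8 lists lay between percentiles 10.35 and 84.93. The collagenase Mmp13 (-7.67), the Wnt antagonist Sfrp2 (-6.68), Col8a2 (-6.64), the tenascin gene Tnn (-6.45) and Sirpa (-6.15) were lowest in S1d/s. Id4 (6.20), the water channel Aqp5 (5.94), Car6 (5.58), the proteoglycan decorin, Dcn (5.44), and Glipr1 (5.27) were highest. Of 18065 probes well above background on both arrays, 1720 were higher by over 1 and 1721 lower by over 1. These percentiles describe the 2 arrays, not the populations.

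In embryos, mouse genes were compared with the same populations in culture on the 298 genes whose probes were well above background on all 6 injected arrays and not on the uninjected one. Among the largest falls relative to the array median were those of the endosomal GTPase Rab5a (-3.88 ± 0.19, SE, n = 6 pairs), cytochrome c, Cycs (-3.72 ± 0.23), Pkd2, the polycystin-2 channel (-3.68 ± 0.21), Zfp960 (-3.43 ± 0.19), Ube2e3 (-3.35 ± 0.22), Lrp12 (-3.34 ± 0.23), Smndc1 (-3.34 ± 0.22), Chsy1 (-3.34 ± 0.21) and Rab2a (-3.28 ± 0.24). Of the list members, the mitotic kinase Aurkb (-2.58 ± 0.33) and the sterol demethylase Cyp51 (-2.51 ± 0.31) fell, and Nrp1 stood at -0.013 ± 0.28 (limma adjusted p = 0.97). The chemokine receptor Ccr9 (2.02 ± 0.22), Ghrh (2.01 ± 0.20), Apoa5 (1.94 ± 0.20), Snai3 (1.90 ± 0.27), the inflammasome sensor Nlrp3 (1.90 ± 0.24), Elf4 (1.84 ± 0.22), the synapsin gene Syn1 (1.80 ± 0.18), Pgm3 (1.74 ± 0.18) and the chemokine Ccl20 (1.30 ± 0.22) rose relative to the array median, and all of these were negative with spike-in scaling. Lrrc52 and Mgl2, not well above background in any culture, were at least 4.55-fold and 3.08-fold higher, though with spike-in scaling Lrrc52 was not called and Mgl2 was at -0.99. Every gene named here apart from Nrp1 had a limma adjusted p of 9.64e-05 or less. In all, 126 genes rose and 106 fell by limma, relative to the array median. The uninjected-embryo array, with no mouse cells, differed from culture in the same direction for all 126 and all 106. Its median difference was 1.48 for the rises (injected 1.35) and -2.14 for the falls (injected -2.04). The probes had been picked as not well above background on that array, so this agreement near the floor does not settle the cause. A response of the injected cells was not tested and is not shown by these changes. Median background-subtracted Cy3 signal of the 126 was 14.9 on injected arrays and 21.4 in culture. Among the 217 genes also well above background on all 6 cultured arrays, a demand made after seeing the data, 49 rose and 106 fell. Under loess scaling 24 genes were higher and 70 lower, and under spike-in scaling 0 higher and 270 lower, against 126 and 106. Mean log2 spike-in signal was 15.7 to 16.1 on injected and 13.1 to 13.8 on cultured arrays, so that scaling lowers every embryo value. Observed and expected spike-in values correlated at 0.86 to 0.90 on injected and 0.98 to 0.99 on cultured arrays. Requiring 4 times the uninjected signal left 29 genes, ignoring the uninjected array gave 10803, and leaving out the embryos with low-passage BC-BMMSC gave 356.

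Within embryos, mouse genes were compared between the high-passage and tumour-derived cells and the low-passage cells to ask whether the condition differs in the host. Only genes without overlap of the groups were ranked. Olfr827 (1.39 ± 0.27, SE, n = 4 against 2) and Lrrc26 (1.25 ± 0.21) had the largest measured positive ratios. Tasp1 (-0.69 ± 0.25), Yipf4 (-0.63 ± 0.22), Slc30a6 (-0.50 ± 0.22), Smarcad1 (-0.49 ± 0.18) and Tcf4 (-0.44 ± 0.18) had the largest negative ones, against a median of all tested genes of 0.52. Golga7b (1.52 ± 0.23) and Klrc3 (1.38 ± 0.17) had higher ratios, yet their Cy3 signal was well above background in both low-passage samples and in none of the other 4, at least 1.69-fold and 1.21-fold lower there. No direction is given for them. Sec14l4 was at least 1.54-fold higher, by a probe not well above background in the low-passage samples. Olfr827, Golga7b, Klrc3 and Lrrc26 had negative differences under loess and with Cy3 alone. Limma called 0 of 5051 genes (smallest adjusted p = 0.0838), with 1111 at an unadjusted p under 0.05. The groups did not overlap in 1762 genes (34.9%), where chance gives 13.33%, with the median of all genes at 0.52. With slide as a block 3441 genes were higher and 462 lower. Only 1 slide held both conditions, so that count rests on the 1 array of high-passage BC-BMMSC against the 1 of low-passage B6-BMMSC. It cannot tell condition from line. Loess gave 69 genes, all lower. Genes also passed without the embryos of either low-passage population, which leaves 1 low-passage array. None of the 10 lists with enough members was called: the medians were -0.0045 for cell cycle, 0.35 for osteoblast, 0.50 for adipocyte, 0.75 for chondrocyte and 0.71 for MSC surface and stroma. They were 0.12 for matrix proteases and inhibitors, 0.0043 for angiogenic factors, -0.032 for interferon response, 0.63 for inflammatory cytokines and 0.71 for macrophage and haematopoietic genes. Lists were called in 5 of 19 alternatives, among them slide and strain as blocks. Without embryos of low-passage BC-BMMSC cell cycle (-0.18) was called lower.

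The change on injection was then compared between the conditions. Rankings here cover only genes whose changes did not overlap between the conditions. The largest positive differences in change were those of Tfap2e (1.25 ± 0.35, SE, n = 4 against 2 populations), Nlrp3 (1.18 ± 0.35), Lix1 (1.09 ± 0.38), Zfp2 (1.08 ± 0.34) and Ptpn13 (1.08 ± 0.40). The largest negative ones were those of Spata5 (-1.71 ± 0.50), the mitochondrial import receptor Tomm70a (-1.71 ± 0.52), the glycogen branching enzyme Gbe1 (-1.65 ± 0.42), Tasp1 (-1.59 ± 0.43) and Oard1 (-1.25 ± 0.42). The median over all 298 genes was 0.21. With spike-in scaling Tfap2e (-2.39), Lix1 (-0.73) and Zfp2 (-0.063) were negative, under loess Nlrp3 (-0.19) and Tfap2e (-0.56) were, and Tfap2e turned in 4 further alternatives and Lix1 in 2. Aurkb differed by -1.32 ± 0.65 and Cyp51 by -1.21 ± 0.60. Limma called 0 of 298 genes (smallest adjusted p = 0.284), with 48 at an unadjusted p under 0.05. Without embryos of low-passage BC-BMMSC 59 genes passed, and under loess 3 did, Ghrh (-2.28), Apoa5 (-1.68) and a clone with no symbol (-1.77), named after their values were seen.

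Embryo RNA was read from the zebrafish arrays, whose probes carried no gene symbol in the tables used here, so that no zebrafish gene or pathway is named. In cell-injected embryos 30 of 30260 transcripts were lower by limma than on the 1 array of embryos given PVP alone and none were higher, with a smallest adjusted p of 0.00692 and 792 transcripts at an unadjusted p under 0.05. Their median Cy3 signal was 99.96 in the PVP embryos and 9.08 in the cell-injected ones. Of the 30, 24 were well above background in PVP embryos, 10 on all 6 injected arrays and 0 with mouse RNA. The lone PVP array was assumed to vary like the others, yet it had 585 non-uniform spots against 0 to 116 on the injected arrays and, as above, fewer probes above background. The comparison does not separate a response to cells from a difference of that array. The count was 0 without the TmMSC-injected embryos, 14 without those of either B6-BMMSC passage, 19 without those of either BC-BMMSC passage and 20 without those of S1d/s. The scanner software's processed signals gave 2556 higher and 4967 lower, quantile-scaled Cy3 3368 and 7189, the authors' deposited ratios 2339 and 4047, and a requirement of signal on every array 0.

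Embryos injected with high-passage and tumour-derived cells were compared with embryos injected with low-passage cells to ask whether the host responds to the kind of cell. Limma called 0 of 30676 transcripts (smallest adjusted p = 0.99997), with 136 at an unadjusted p under 0.05. The groups did not overlap in 1426 transcripts (4.65%), where chance gives 13.33%. The embryos grouped otherwise: across transcripts, those with low-passage BC-BMMSC and with S1d/s correlated at 0.955 and those with the 2 B6-BMMSC passages at 0.940, while low-passage BC-BMMSC and high-passage BC-BMMSC correlated at 0.421. TmMSC-injected embryos lay between, at 0.727 to 0.801 with every other.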

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

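All tests in this part were chosen only after the result was seen, except that of the signal of embryo RNA, whose prediction was written before.

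2 of 26 groups of 4 or 6 arrays had a sample far from the others, where chance gives about 1 in 20. The mean over the osteoblast list was 0.954 in cultured TmMSC, against -0.204 in the nearest of the 4 high-passage and tumour-derived cultures. The mean over the chondrocyte list was -0.833 in cultured S1d/s, against -0.222 in the nearest. The mean over the interferon response list moved in opposite directions at high passage, by 2.22 in B6-BMMSC and -0.625 in BC-BMMSC, and with 1 pair each the difference was not tested.

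Of 298 mouse genes, 232 differed between embryos and culture, and 3 explanations were weighed. Embryo RNA on mouse probes stayed open. Of the genes called higher on injection, 100% were also higher on the uninjected-embryo array than in culture. The median difference was 1.48 there and 1.35 on the injected arrays. Of the genes called lower, 100% were lower there too, at a median of -2.14 against -2.04. The probes had been picked as not above background on that array, so its signal was near the floor and the part of embryo RNA was not decided. A small share of mouse RNA could act as well. The highest median excess over the uninjected array was 0.754% of the cultured level. Scaled by the spike-in probes it was 0.102%, and both B6-BMMSC arrays then fell below 0. For chance assignment of arrays, 1 of 32 swaps, the real one, gave 232 genes and the highest other 133. Each swap mixed embryo and culture RNA on both sides, with probes still picked on the injected arrays. A lower count was thus fixed in advance, and this decides nothing about chance. A response of the cells to the embryo was not tested. These changes cannot by themselves show one, since signal near the floor gave the same directions on the array without mouse cells.

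Cell cycle genes were higher in high-passage and tumour-derived cultures, by camera at a preset correlation. At an estimated correlation camera did not call them (adjusted p = 0.83). Slide, 1 low array and a biological difference were weighed for this. Slide, as inferred from the files, was argued against for 2 pairs of arrays only. The smaller of their within-slide mean differences was 0.796 on the log2 scale. Each pair set 1 array against 1 of another line, and the larger difference, 1.95, involved low-passage B6-BMMSC. The spread used was over genes, not arrays, and condition cannot be told from line there. A low level in low-passage B6-BMMSC alone stayed open: without that array the difference was 0.392, and 3 of the 4 other arrays lay above low-passage BC-BMMSC. High-passage B6-BMMSC, with a mean of 0.32, lay below low-passage BC-BMMSC, with 0.63. Faster division of the later cells, as a biological difference, was not tested as a cause of the remainder, and 6 arrays could not settle it.

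On the zebrafish arrays, embryos with low-passage BC-BMMSC and S1d/s differed from the other 4 in 12271 transcripts by limma. This split was picked after the values were seen, and its count was the highest of all splits of 2 arrays against 4. TmMSC-injected embryos lay between the sides, at 0.801 and 0.727 with these 2 and 0.761 to 0.793 with the other 3. Median Cy3 signal went with this split, at 207 and 260 on these 2 arrays, 178 with TmMSC and 112 to 134 on the other 3, and was not tested as a cause. Low-passage cells against the other 4 gave 0 transcripts by limma, with 136 at an unadjusted p under 0.05, but the split has 1 low-passage array on each side, so this decides nothing about passage. Slide, again as inferred, was argued against, since high-passage B6-BMMSC, on the same slide as the 2, correlated with the BMMSC arrays of the other slide by 0.475 more. With the TmMSC array of that slide it correlated at 0.793, against 0.448 at most on its own. Hybridisation to the zebrafish array stayed open: distances between embryos on the 2 array designs correlated at 0.125 (exact one-sided p = 0.257). A difference between the embryo batches could produce the same split, and no label records one.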

How the results depend on the processing

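With 1 array per population and setting, every result rests on few arrays, and weak signal over background limits how many mouse genes can be tested in embryos. Where a left-out array leaves a group with 1 array, that array was assumed to vary like the others. Slide as a random block, for high-passage and tumour-derived against low-passage cells in culture and in embryos, and the demand for signal on all 6 cultured arrays were chosen after seeing the data. Slide as a fixed block left no residual freedom in the fits of 3 groups and was not run there, where slide was a random block instead. The limit of 4 times the uninjected signal gave no list value for mouse genes in embryos by condition. The cause was not tested for any difference below unless stated.

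Counts of 0 genes stayed 0 under all 15 alternatives for high- against low-passage cells, for TmMSC and S1d/s against low-passage and against high-passage cells, and under all 16 for the embryo transcripts by condition. For high-passage and tumour-derived against low-passage cultures 16 of 17 gave 0, and leaving out arrays gave 0 to 3. With an estimated correlation in camera, and with fry in one direction or either, 0 lists were called in each of the 4 comparisons of cultured cells. For high-passage and tumour-derived against low-passage cells slide as a block gave 3 lists in place of 7, strain as a block 5, no filter on dim probes and every probe tested 6 each, without cholesterol synthesis, and left-out arrays 3 to 8. For high- against low-passage cells no filter gave 3 in place of 6, without interferon response, MHC class I and matrix proteases and inhibitors. Every probe tested gave 4, without the last 2 of these, the cell line as a block 5, slide as a random block 7, with hypoxia and glycolysis, median centring 8, with these and heat and cold stress, and left-out arrays 4 to 7. For TmMSC and S1d/s against low-passage cells no filter gave 6 in place of 7, without interferon response, strain as a block 6, with p53 targets and CDK inhibitors new, slide as a random block 8, with p53 targets, and left-out arrays 3 to 8. Against high-passage cells quantile-scaled Cy3 gave 3 in place of 2, median centring and no filter 4 each, slide as a random block 5 and strain as a block 6, and p53 targets were new in all of these. With them came ribosomal proteins under median centring, no filter and the random block, osteoblast genes under both blocks, and interferon response and CDK inhibitors under strain. The count was 3 to 6 with arrays left out. For mouse genes in embryos by condition, lists came to 11 with no use of the uninjected array and 1 each with slide as a block, slide as a random block and strain as a block, and to 0 to 1 with arrays left out.

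Pairing was tested by the replicate block. High- against low-passage cells gave 0 genes with the cell line as a block, which ended the call of matrix proteases and inhibitors, and injected against cultured cells gave 235 genes without the block of populations against 232 with it. The change on injection gave 0 genes without it. The block changed no other call of a named gene or list.

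In high-passage and tumour-derived against low-passage cultures 13 of 996 values of named genes turned. Values were Cxcl10 -0.83, Eng 0.056, Actc1 0.43, Acta1 0.41 with slide as a block. With arrays left out they ranged as follows: Acta1 -1.34 to 0.00087, Actc1 -1.30 to 0.038, Cdkn2a -2.73 to 1.01, Cdkn2b -5.16 to 1.46, Eng -1.16 to 0.46, Kdr -0.59 to 0.11, Krt19 -3.21 to 0.68, Mki67 -0.071 to 2.02, Thy1 -4.90 to 0.93.

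In high- against low-passage cultures 24 of 894 turned. Trp53 -0.092 was the value with every probe tested. Flt1 0.059 was the value with median centring. Cdkn2b 1.04 was the value with slide as a random block. With arrays left out the ranges were Alpl -3.01 to 0.53, Btg2 -2.40 to 0.29, Cd14 -0.69 to 0.32, Cdkn1b -1.77 to 0.53, Cdkn2a -1.88 to 2.40, Cdkn2b -3.66 to 2.96, Comp -2.21 to 0.15, Cxcl10 -1.34 to 4.46, Eng -1.29 to 0.33, Flt1 -0.53 to 0.25, Krt18 -0.72 to 1.37, Lpl -2.58 to 0.17, Mki67 -0.45 to 1.64, Omd -4.79 to 1.04, Pparg -2.20 to 0.045, Trp53 -0.11 to 0.22, Zbp1 -0.45 to 2.99.

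In TmMSC and S1d/s against low-passage cultures 10 of 847 turned, all with arrays left out: Actc1 -3.20 to 0.086, Cd74 -0.98 to 0.30, Col11a1 -2.83 to 0.35, Col1a1 -2.68 to 0.48, Cxcl10 -0.32 to 4.68, Cxcl5 -2.99 to 0.29, Flt1 -2.30 to 1.67, Mmp19 -1.77 to 0.31.

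In TmMSC and S1d/s against high-passage cultures 18 of 852 turned. Values were Ets1 -0.055, Eng -0.021 with slide as a random block. With strain as a block the values were Eng -0.23, Hspb1 -0.78. Left-out arrays gave Actc1 -3.22 to 0.071, B2m -0.34 to 1.72, Cd14 -0.10 to 0.91, Col1a1 -2.01 to 1.15, Eng -0.72 to 1.24, Erap1 -0.071 to 1.73, Ets1 -0.098 to 0.28, Fabp4 -0.86 to 2.597, Hspb1 -0.69 to 3.00, Ifit3 -3.49 to 1.19, Mmp13 -0.21 to 7.46, Mmp19 -0.67 to 1.41, Spp1 -0.34 to 4.58.

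For mouse genes in embryos against culture the count was 94 with loess, 270 with spike-in scaling (all lower), 29 with a limit of 4 times the uninjected signal, 10803 with no use of the uninjected array, 155 (49 higher, 106 lower) of 217 with signal on all 6 cultured arrays, and 221 to 356 with arrays left out. The limit, the unused array and the demand for signal in culture change how many genes are tested. Of 510 values of named genes 21 turned, 8 lost their call and 1 gained one. With spike-in scaling the values were Ccr9 -1.13, Ghrh -1.49, Apoa5 -1.61, Snai3 -0.24, Nlrp3 -3.46, Elf4 -3.39, Syn1 -2.19, Mgl2 -0.99, Pgm3 -2.55, Ccl20 -2.497. Nrp1 0.018 was the value with the software's processed signals. Nrp1 0.28 was the value with loess. Nrp1 0.0011 was the value with the authors' deposited ratios. Nrp1 0.39 was the value with slide as a block. With no use of the uninjected array the values were Pgm3 -1.21, Nrp1 0.61. Left-out arrays gave Nrp1 -0.47 to 0.30.

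For mouse genes in embryos by condition the count was 69 with loess, 3903 with slide as a block, 2656 with slide as a random block, and 0 to 3909 with arrays left out. The fixed slide block rests on 1 pair of arrays of different lines, as given above. Of 660 values of named genes 135 turned and 96 gained a call. With Cy3 alone the values were Golga7b -4.27, Olfr827 -1.13, Klrc3 -2.90, Lrrc26 -1.93, Ccne1 -0.71, Aurkb 0.51, Aen -1.71, Cdkn1b 0.80, Col3a1 -1.08, Cidea -0.80, Dgat2 -1.81, Hapln1 -0.76, Timp4 -1.31, Mmp17 -1.21, Fgf1 -0.48, Ifih1 0.88, C1qa -0.88, Kdr -0.55, Emcn -2.79, Krt8 -0.42, Cyp51 0.35. With spike-in scaling the values were Golga7b -4.41, Olfr827 -1.27, Klrc3 -3.04, Lrrc26 -2.07, Ccne1 -0.85, Aurkb 0.37, Aen -1.85, Cdkn1b 0.66, Col3a1 -1.22, Cidea -0.94, Dgat2 -1.95, Hapln1 -0.90, Timp4 -1.45, Mmp17 -1.36, Fgf1 -0.62, Rsad2 -0.048, Ifih1 0.74, C1qa -1.02, Kdr -0.69, Emcn -2.93, Krt8 -0.56, Cyp51 0.21. With the software's processed signals the values were Golga7b -0.67, Klrc3 -0.95, Lrrc26 -0.16, Ccne1 -0.67, Aurkb 0.56, Aen -1.80, Cdkn1b 0.88, Col3a1 -1.11, Cidea -1.02, Dgat2 -1.61, Hapln1 -0.53, Timp4 -1.02, Mmp17 -1.38, Fgf1 -0.0088, Ifih1 0.91, C1qa -0.60, Kdr -0.38, Emcn -1.93, Krt8 -0.47, Cyp51 0.35. With a limit of 4 times the uninjected signal the values were Col3a1 -0.26, Emcn -0.011. Pdk1 0.022 was the value with every probe tested. With loess the values were Golga7b -0.92, Olfr827 -0.33, Klrc3 -0.26, Lrrc26 -0.44, Ccne1 -0.23, Aurkb 0.062, Aen -0.36, Cdkn1b 0.13, Col3a1 -0.62, Cidea -0.17, Dgat2 -0.29, Hapln1 -0.069, Timp4 -0.59, Mmp17 -0.12, Fgf1 -0.096, Ifih1 0.070, C1qa -0.13, Aif1 -0.0076, Kdr -0.45, Emcn -0.48, Krt8 -0.22. With the authors' deposited ratios the values were Golga7b -0.67, Klrc3 -0.83, Lrrc26 -0.12, Ccne1 -0.67, Aurkb 0.56, Aen -1.80, Cdkn1b 0.88, Col3a1 -1.11, Cidea -1.02, Dgat2 -1.61, Hapln1 -0.44, Timp4 -1.02, Mmp17 -1.38, Fgf1 -0.0088, Ifih1 0.91, C1qa -0.60, Kdr -0.38, Emcn -1.93, Krt8 -0.47, Cyp51 0.35. Values were Fas -0.084, Insig1 -0.28 with slide as a block. Values were Fas -0.010, Insig1 -0.13 with slide as a random block. Insig1 -0.050 was the value with strain as a block. With no use of the uninjected array the values were Tcf4 0.016, Ccne1 -0.44, Aurkb 0.031, Aen -0.44, Fas -0.071, Dgat2 -0.0022, Mmp17 -0.24, Ets1 0.061, Ifih1 0.048. Left-out arrays gave Aurkb -0.47 to 0.16, C1qa -0.0037 to 1.60, Cdkn1b -0.082 to 0.062, Col3a1 -0.32 to 0.81, Cyp51 -0.58 to 0.042, Emcn -0.14 to 1.12, Fas -0.18 to 0.25, Ifih1 -0.51 to 0.23, Insig1 -0.23 to 0.25, Kdr -0.17 to 1.31, Krt8 -0.088 to 0.55, Pdk1 -0.79 to 0.0037.

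For the change on injection by condition the count was 3 with loess and 0 to 59 with arrays left out, and 27 of 317 values of named genes turned and 4 gained a call. With Cy3 alone the values were Tfap2e -1.32, Nrp1 0.0071, Ccl20 -0.63. With spike-in scaling the values were Tfap2e -2.39, Lix1 -0.73, Zfp2 -0.063, Ccl20 -1.70. With the software's processed signals the values were Tfap2e -0.90, Lix1 -0.24, Nrp1 0.036, Ccl20 -0.70. With loess the values were Tfap2e -0.56, Nlrp3 -0.19, Ccl20 -0.29. With the authors' deposited ratios the values were Tfap2e -0.85, Lix1 -0.21, Nrp1 0.0099, Ccl20 -0.73. Values were Nrp1 0.18, Cxcl16 0.17 with slide as a block. With no use of the uninjected array the values were Tfap2e -0.037, Nrp1 0.93. Left-out arrays gave Aurkb -2.64 to 0.0016, Cxcl16 -0.84 to 0.18, Nrp1 -0.98 to 0.023.

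For embryo transcripts of cell-injected against PVP-injected embryos the count was 7523 with the software's processed signals, 1.1e+02 with median centring, 10557 with quantile-scaled Cy3, 61 with no filter, 0 with signal on every array, 6386 with the authors' deposited ratios, 48 with every probe, 19 with slide as a block and 0 to 20 with arrays left out. Setting each of the other 6 arrays apart in place of the PVP array gave 0 each.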

Other observations

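All tests in this part were chosen only after the result was seen.

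Cultured cells differed by line in genes that did not follow passage. BC-BMMSC, the only BALB/C cells, had lower Mllt3 (-5.24), Mtap (-4.38), Thumpd1 (-4.28), Focad (-3.86), Eml2 (-3.57) and Pop4 (-3.12) than C57BL/6 cells, and higher Xist (8.996), Cd24a (5.06), Cthrc1 (3.90), Sdr39u1 (3.85), Rbm45 (3.03) and Itgb3 (2.00). These are among 35 genes called by limma for the 2 BC-BMMSC arrays against the other 4. The 2 B6-BMMSC arrays against the other 4, which divides the C57BL/6 cells, gave 50. Strain cannot be told from cell line or donor here.

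A first hypothesis was that the weak signal in embryos on probes free of embryo signal came from the injected cells. On these probes, deviations of the injected arrays correlated with those of the cultured array of their own population at a mean of 0.125 (exact one-sided p = 0.00556 over 720 pairings). RNA of the injected cells could give this, but not evenly over the populations. Over the 298 genes tested against culture, correlations of injected and cultured arrays of a population ran from only -0.088 to 0.14. On the probes free of embryo signal, the own correlations were 0.052 for low-passage B6-BMMSC, 0.045 for high-passage B6-BMMSC, 0.068 for low-passage BC-BMMSC, 0.154 for high-passage BC-BMMSC, 0.076 for TmMSC and 0.354 for S1d/s. The own population was highest in the last 3 only.

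A second hypothesis was that BC-BMMSC lack a stretch of genome around Cdkn2a rather than differing in scattered genes. In a segment of 16 measured neighbours 7 genes were lower by over 1 in both BC-BMMSC arrays, against 372 of 14477 genes (2.57%) in all. The segment was cut after the values were seen, to begin and end at low genes. Of 14139 windows elsewhere 0% held as many, with a highest count of 5, which suggests a shared cause in the segment. TmMSC and S1d/s were low at Cdkn2a and Cdkn2b only. A deletion could produce this, but so could silencing, and DNA was not measured.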
